A study of Mus musculus with 4 samples.

How the data were processed

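Messenger RNA was measured in 4 libraries of mouse fully grown germinal vesicle oocytes, the stage at which the oocyte is arrested in meiotic prophase with an intact nucleus. The oocytes came from unprimed females at postnatal day 20 and were held in prophase with milrinone, per the labels' protocols. Each live oocyte was imaged in bright field and assigned by a deep learning pipeline to the non-surrounded nucleolus (NSN) or the surrounded nucleolus (SN) chromatin class. In SN oocytes condensed chromatin forms a ring around the nucleolus; in NSN oocytes it does not. RNA was captured with oligo(dT), so transcripts with a short poly(A) tail can be under-represented and a change in tail length can appear as a change in level. There were 2 libraries per class, named by the replicate number in the labels, and 15 oocytes per class. How those 15 oocytes were divided between the libraries of a class is not stated in the labels. Nothing in the labels says that the replicates came from separate animals, so every p-value measures only the spread between these libraries, which may be technical.

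The authors deposited 1 table of 48574 RefSeq mRNA models, of which 24159 are curated and 24415 are predicted, belonging to 17945 genes by gene ID. HISAT2, Bowtie2, RSEM and the mm10 build are named in the submitters' processing notes, without versions or roles. The deposited values include estimated counts per transcript, as RSEM gives them, and 59.8% of these estimated counts are not whole numbers. The authors' TPM values (transcript abundances scaled to a common sum) add up to 999980.4 to 999983.0 in each library, and their FPKM values (fragments per kilobase, scaled to depth) were used here only to derive an effective length per gene. The authors' normalized read counts, a depth-scaled signal per the file headers, were checked to equal the estimated count rounded up and multiplied by 1 factor per library, and were not tested. Class averages were not used here. The authors' own comparison of SN with NSN was deposited as a log2 ratio and an unadjusted p-value per transcript, with the tool behind it not given in the sources used here. RSEM divides a read that matches several models or near-identical genes between them by likelihood, so values of single models and of close paralogs carry an error that no test here contains.

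Estimated counts were summed per gene and rounded to whole numbers. Totals ranged from 32307398 to 37023401 estimated counts per library, so that a floor of 3 counts corresponds to between 0.081 and 0.0929 CPM, the count scaled to the library total. Intervals and floors cover counting error only, since reads amplified by PCR are not independent molecules. Genes were kept by the filterByExpr rule of edgeR 4.0.16 in R 4.3.3, which left 13426 genes, and scaled by TMM factors. SN was compared with NSN by edgeR's quasi-likelihood test with robust dispersion, and genes were called at a Benjamini-Hochberg adjusted p of 0.05. Log2 fold changes are SN over NSN, with a standard error (SE) derived from the F statistic. The same test was run on 29835 transcripts. Isoform shares were tested with edgeR's diffSpliceDGE and its Simes p per gene in 7000 genes with at least 2 models past the filter. Gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, and again with the correlation estimated. Locations are those of the RefSeq annotation of GRCm38, the assembly that mm10 names, matched by gene ID for 17894 genes.

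The tests, the 23 gene lists and the rule for named genes were fixed before the data were examined. By that rule, because fewer than 10 genes passed, genes were ranked by unadjusted p: the 12 higher in SN and the 12 higher in NSN with both libraries of one class above both of the other and a mean of at least 5 CPM in the higher class, leaving out predicted and numbered gene models. The 2 members of each list with the smallest unadjusted p were also named, except where a gene is not used here, as were Zp3, Gdf9, Ddx4, Amh and Inha, and the 3 genes with the smallest adjusted p for isoforms and transcripts. In simulated counts for the comparison of genes (13225 genes, libraries and dispersions as measured), the edgeR test recovered 55.2% of 1.5-fold, 94% of 2-fold and 100% of 4-fold changes with 15 false calls, where DESeq2 made 20. In simulated counts for transcripts (26536), it recovered 0% of 1.5-fold, 14.9% of 2-fold and 53% of 4-fold changes with 12 false calls, where DESeq2 made 292. For isoform shares (6336 simulated genes), 65% of 60 genes with 2 models moved 4-fold in opposite directions were recovered, with 16 false calls. The list test gave p under 0.05 for 1 of 20 random lists. Changes were placed only in genes or transcripts with a mean of at least 5 CPM, so the recovery rates do not cover rarer ones. These simulations contain no differences between libraries beyond the fitted dispersion.

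Alternatives were DESeq2 1.42.0, limma-voom, other scalings (median of ratios, upper quartile, library size alone), no filter or a mean count of at least 50, limma-trend on log2(TPM + 1) or log2(TPM + 0.1), the TPM test limited to genes with a mean TPM of at least 1, a fold of at least 2, the replicate number as a block, and each library left out in turn. For lists, fry was also run. Added after seeing the data were the removal of trends with effective length and GC content (known for 92.4% of the tested genes), cyclic loess, limma's diffSplice, and curated models alone. Library size alone moved the median log2 of all genes by -0.143, and TPM by -0.122 to -0.168, so values under those scalings are read relative to that shift. Where 1 library was left out, the lone library of a class was assumed to vary like the other class. The deviation of that lone library then counts as a class difference, so calls in these settings are no evidence of one. The 13 mitochondrially encoded genes of a fixed list are not analysed here.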

Results

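Poly(A)-selected RNA was profiled in live-sorted mouse oocytes of the NSN and SN chromatin classes, with 2 libraries per class and 30 oocytes in all. NSN replicates 1 and 2 held 32307398 and 32541920 estimated counts. SN replicates 1 and 2 held 37023401 and 36922573, so both SN libraries were deeper. Between 16046 and 16322 genes had at least 1 count in a library. The 100 most abundant genes took 31.8% and 30.4% of the counts in the NSN libraries and 36.1% and 32.4% in the SN libraries. Across genes, log2 CPM correlated at 0.986 between the NSN libraries and at 0.986 between the SN libraries, against 0.984 to 0.987 between libraries of different classes. Genes are not independent replicates.

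The comparison asked which transcripts differ in level between oocytes whose chromatin class was predicted from bright-field images. No gene's difference between SN and NSN passed the test: edgeR's quasi-likelihood test called 0 of 13426 genes. An unadjusted p under 0.05 was reached by 1004 genes, 539 of them higher and 465 lower in SN, DESeq2 called 46 genes and limma-voom 0. The gene with the smallest adjusted p was Cradd, an adaptor of the caspase-2 death complex, at 41.6 ± 5.87 CPM in NSN and 73.6 ± 1.31 CPM in SN (SD, n = 2 each; log2 0.82, SE 0.11, edgeR adjusted p = 0.131). Cradd was called without NSN replicate 1, without SN replicate 1 and without SN replicate 2. Genes of the oocyte itself did not pass either. Zp3, a zona pellucida glycoprotein, was at 6656 ± 621 CPM in NSN and 8177 ± 1290 CPM in SN (log2 0.30, SE 0.20). Its log2 ranged from 0.133 without SN replicate 1 to 0.453 without SN replicate 2. It flipped with cyclic loess (-0.037), a setting added after seeing the data. Gdf9, an oocyte growth factor, was at 4215 ± 237 and 4519 ± 742 CPM (log2 0.10, SE 0.18), and its direction flipped without SN replicate 1 (-0.072) and with cyclic loess (-0.197). Ddx4, a germ cell RNA helicase, was at 39.4 ± 2.7 and 43.3 ± 11.7 CPM (log2 0.14, SE 0.17; SD, n = 2 each) and flipped without SN replicate 2 (-0.165). Of the 46 genes called by DESeq2, 45 were higher in SN, and the first by adjusted p was Calm2. The 46 had a median log2 CPM of 9.32, against 3.68 for all tested genes. Between 8 and 10, 84.3% of all genes were higher in SN. The direction of the 46 therefore cannot be told apart from the shift of abundant genes. Genes called higher and lower in SN numbered 24 and 23 on log2(TPM + 1), 11 and 4 with library size alone, and 44 and 0 with the replicate block. DESeq2 called 13 genes for replicate 2 against replicate 1. Its 20 false calls in simulated counts came beside changed genes, and its correct calls were not counted there. Those 20 therefore give no share of false calls among the 46. The edgeR count rose to 289 without SN replicate 2, 27 without SN replicate 1 and 2 without either NSN library, to 15 with library size alone or with no low-count filter, and limma-trend gave 47 on log2(TPM + 1).

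The 12 named genes higher in SN in both libraries did not pass the test (edgeR adjusted p = 0.131 to 0.609). With SN replicate 2 left out, the SN class was SN replicate 1 alone. For genes above a log2 CPM of 10, SN replicate 1 differed from the other libraries by a log2 of 0.35. The 24 named genes in both directions were also ranked on all libraries. Calls with a library left out are therefore no support for them. With no low-count filter Cradd, Mfap1b, Lcmt2, Crabp2, Cnpy4, Bloc1s2, Calm2 and Tpm3 were called, with library size alone and with the length and GC trend removed Cradd, by DESeq2 Calm2 and Grm2, and in each TPM setting Calm2. Cradd (gene ID 12905) lies on chromosome 10 at 95174739 to 95324138 (GRCm38). Mfap1b, a spliceosome-associated factor with a near-identical copy in the mouse genome that makes its count uncertain, was at 54.7 ± 1.09 CPM in NSN and 81.8 ± 9.08 CPM in SN (SD, n = 2 each; 1.5-fold). Lcmt2, a tRNA-modifying methyltransferase on chromosome 2 at 121137292 to 121140698, was at 26.5 ± 0.687 and 43.6 ± 7.32 CPM, or 1.65-fold higher in SN. Crabp2, a cytoplasmic retinoic acid binding protein on chromosome 3 at 87948693 to 87953372, was at 140.9 ± 6.57 and 200.6 ± 11.3 CPM. Aldh1a2, which makes retinoic acid from retinal, was at 82.9 ± 10.5 and 112.5 ± 0.576 CPM. Calm2, a calmodulin gene, was at 477.8 ± 46 CPM in NSN and 708.7 ± 62.6 CPM in SN, or 1.48-fold. Grm2, a metabotropic glutamate receptor, was at 226.8 ± 10.6 and 309 ± 23 CPM, or 1.36-fold. Tpm3, a tropomyosin, was 1.48-fold higher in SN, and Bloc1s2, which acts in lysosome-related organelle formation, 1.48-fold. Cnpy4, Epp13 and Llph were 1.40-fold, 1.43-fold and 1.35-fold higher.

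The 12 named genes higher in NSN did not pass either (edgeR adjusted p = 0.38 to 0.662). Ube2s was called by DESeq2, with library size alone and in each TPM setting, Pthlh in each TPM setting, and Fbxo33 with library size alone and with no low-count filter. Fbxo33, an F-box protein of ubiquitin ligases on chromosome 12 at 59200655 to 59221961, was at 66.5 ± 1.84 CPM in NSN and 45.9 ± 4.36 CPM in SN (SD, n = 2 each), 1.45-fold higher in NSN. Cad, which carries the initial enzymes of pyrimidine synthesis, lies on chromosome 5 at 31054620 to 31078479 and was at 6.83 ± 0.605 and 3.49 ± 0.143 CPM, 1.96-fold higher in NSN. Ube2s, the ubiquitin-conjugating enzyme of the anaphase-promoting complex, was at 498.1 ± 15.9 CPM in NSN and 378.3 ± 8.97 CPM in SN, 1.32-fold higher in NSN. Pthlh, which encodes parathyroid hormone-related peptide, was 1.59-fold higher in NSN at 12.5 ± 0.494 against 7.82 ± 0.918 CPM. The cell surface receptors Celsr1 and Plxnb2 were 1.40-fold and 1.38-fold higher, and the splicing factor Srsf11 1.53-fold. Abhd17a, Relch, Ccdc68, Sel1l and Inpp5a were 1.43-fold, 1.38-fold, 1.65-fold, 1.31-fold and 1.35-fold higher in NSN. Of all tested genes, 39% had both libraries of one class above both of the other, where chance gives 33.3%.

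**Figure D1:**
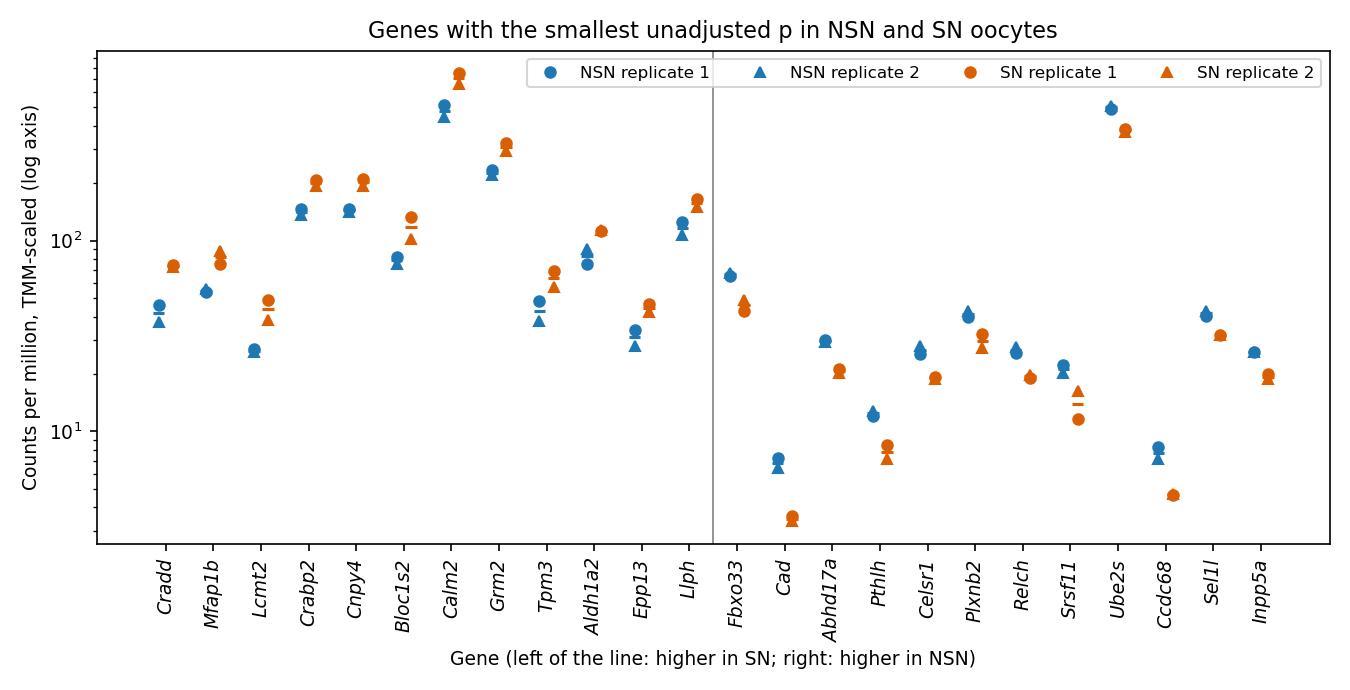
TMM-scaled CPM (log axis) of the 24 named genes in each of the 4 libraries, with a short line at each class mean. The 12 genes left of the vertical line were higher in both SN libraries and the 12 to the right in both NSN libraries; none passed the adjusted threshold, and the smallest adjusted p was 0.131 for Cradd.

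Lists of genes for oocyte identity and for protein synthesis, respiration and turnover lay slightly higher in SN. With cyclic loess, added after seeing the data, the oocyte list (-0.064) and the proteasome (-0.016) flipped. With the length and GC trend removed, also added after seeing the data, the oocyte list was called and the other 4 were not (adjusted p = 0.191 to 0.782), and the proteasome median was -0.005. The list of oocyte identity and maternal effect genes had a median log2 of 0.15 over 51 tested members, 44 of them higher in SN (camera adjusted p = 4.3e-05; adjusted p = 0.947 with an estimated correlation). At an unadjusted p under 0.05, 11 members were higher and 0 lower. The members had a median log2 CPM of 10.58, and all genes above 10 had a median log2 of 0.26, with 98.4% higher in SN. The list was not compared with other genes of that abundance, so its shift cannot be told apart from that of abundant genes. Its members with the smallest unadjusted p were Obox1 at 1266 and 1124 CPM in NSN and 2037 and 1457 CPM in SN, and Obox2 at 1939 and 1690 CPM against 3036 and 2250 CPM. Both are homeobox genes with close paralogs whose reads are shared. Cytosolic ribosomal protein genes had a median of 0.10 with 69 of 82 higher in SN (camera adjusted p = 4.3e-05; adjusted p = 0.947 with an estimated correlation), with Rpl39 at log2 0.34 (SE 0.13). Nuclear-encoded oxidative phosphorylation genes had a median of 0.12 with 59 of 77 higher (camera adjusted p = 0.000106; adjusted p = 0.947 with an estimated correlation), with Atp5g2, an ATP synthase subunit, at 0.36 (SE 0.11) and Sdhc, a subunit of complex II, at 0.29 (SE 0.10). RNA polymerase II transcription machinery had a median of 0.07 with 52 of 82 higher (camera adjusted p = 0.0211; adjusted p = 0.947 with an estimated correlation), with Taf13 at 0.37 (SE 0.09) and Taf8 at 0.31 (SE 0.09). The proteasome had a median of 0.07 with 29 of 40 higher (camera adjusted p = 0.0417; adjusted p = 0.947 with an estimated correlation), with Psmc2 at 0.28 (SE 0.11) and Psmb7 at 0.34 (SE 0.14).

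None of these 5 lists was called with an estimated correlation, and edgeR called 0 of their members over all genes and 0 adjusted over the list alone. No list was called without NSN replicate 2 or without SN replicate 1. The ribosomal protein median was then -0.036 and -0.025, and the oxidative phosphorylation median -0.003 and -0.008, against 0.261 and 0.222 without NSN replicate 1 and 0.227 and 0.197 without SN replicate 2. The oocyte median was 0.079 without SN replicate 1 and 0.255 without SN replicate 2. Without SN replicate 1 the RNA polymerase II median was 0.024 and the proteasome median 0.04. These lists also moved with another division of the libraries. Replicate 2 against replicate 1 gave a ribosomal protein median of -0.27 (camera adjusted p = 9.46e-40), an oxidative phosphorylation median of -0.205 (camera adjusted p = 1.27e-25) and an oocyte list median of -0.166 (camera adjusted p = 0.000757). Within replicate number 1 and within replicate number 2, SN exceeded NSN by a median log2 of 0.09 and 0.14 for ribosomal proteins, 0.08 and 0.12 for oxidative phosphorylation, and 0.21 and 0.12 for the oocyte list. The shift moved with abundance: the 125 genes above a log2 CPM of 10 had a median log2 of 0.26, with 98.4% higher in SN, whereas the 3055 genes between 2 and 4 had a median of -0.06, with 39.9% higher. For the genes above 10, SN replicate 1 differed from the mean of the other libraries by a log2 of 0.35 and NSN replicate 2 by -0.272. NSN replicate 1 and SN replicate 2 differed by -0.068 and -0.01.

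Lists for chromatin, nuclear export, mRNA turnover and the spindle did not pass. The themes of 5 lists (export, deadenylation, histone modification, remodelling and microtubules) are also named in the study's description of these samples, so those lists are not independent evidence of a direction. RNA and protein export factors had a median log2 of -0.02 with 22 of 48 higher in SN (camera adjusted p = 0.743); Rbm8a, of the exon junction complex, was at 0.30 (SE 0.11) and Rangap1, the Ran GTPase activator, at -0.63 (SE 0.25). Deadenylation and mRNA decay genes had a median of -0.05 with 19 of 50 higher (camera adjusted p = 0.325), with Ythdf2, an m6A reader, at -0.30 (SE 0.10) and Exosc2, an exosome subunit, at 0.54 (SE 0.20). Histone modifying enzymes had a median of -0.03 with 28 of 78 higher (camera adjusted p = 0.185), with Sirt1, a deacetylase, at -0.46 (SE 0.14) and Kdm6b, a histone H3 demethylase, at 0.27 (SE 0.10). Chromatin remodelling complexes had a median of -0.03 with 28 of 61 higher (camera adjusted p = 0.842), with Npm2, a histone chaperone of the egg, at 0.50 (SE 0.17) and Baz1b at -0.30 (SE 0.10). Spindle and microtubule genes had a median of 0.01 with 43 of 82 higher (camera adjusted p = 0.779), with Spast, a microtubule-severing enzyme, at -0.26 (SE 0.09) and Haus5 at -0.39 (SE 0.15). In each of these 5 lists the main edgeR test called 0 members over all genes and 0 adjusted over the list alone. DESeq2 called the members Npm2 and Tacc3, and Npm2 was also called with the replicate block and on log2(TPM + 0.1). Exosc2 and Kdm6b were called with the length and GC trend removed and the replicate block added. Calls of members with a library left out are not listed here. At an unadjusted p under 0.05, members higher and lower in SN numbered 1 and 1 for export, 3 and 3 for deadenylation and 1 and 5 for histone modification. They numbered 4 and 4 for remodelling and 4 and 2 for the spindle.

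Other lists of oocyte biology did not pass the list test either. The nuclear pore complex had a median log2 of -0.05 (camera adjusted p = 0.779), with Nup43 at 0.23 (SE 0.10) and Nup188 at -0.20 (SE 0.10). Meiotic cell cycle genes had a median of 0.02 (camera adjusted p = 0.779), with Mad2l1, of the spindle checkpoint, at 0.34 (SE 0.12) and Ube2s at -0.40 (SE 0.11). Cytoplasmic polyadenylation and translational control had a median of 0.02 (camera adjusted p = 0.993), with Zar1l at 0.45 (SE 0.15) and Lsm14b at -0.31 (SE 0.10). DNA methylation and imprint protection had a median of -0.06 (camera adjusted p = 0.499), with Gadd45b at -0.57 (SE 0.26) and Kdm1b, a histone demethylase needed for maternal imprints, at -0.22 (SE 0.10). The spliceosome had a median of 0.04 (camera adjusted p = 0.185), with Srsf11 at -0.61 (SE 0.17) and Snrpb at -0.37 (SE 0.12). Small RNA pathways had a median of -0.06 (camera adjusted p = 0.779), with Mael at 0.24 (SE 0.09) and Henmt1 at 0.31 (SE 0.12), and prophase recombination and DNA repair a median of -0.01 (camera adjusted p = 0.779), with Chek1 at 0.22 (SE 0.11) and Xrcc6 at 0.22 (SE 0.10). Cholesterol synthesis had a median of -0.03 (camera adjusted p = 0.779), with Idi1 at 0.50 (SE 0.14) and Nsdhl at 0.30 (SE 0.10), and stress response and apoptosis a median of 0.01 (camera adjusted p = 0.908), with Hspb1 at 0.92 (SE 0.23) and Atf3 at -0.89 (SE 0.31). In the main edgeR test these lists had 0 members called over all genes and 0 adjusted over the list alone. DESeq2 called the members Mad2l1, Ube2s and Zar1l, and Zar1l was also called with the replicate block. Members called with a library left out are not listed. In 6 of the 22 lists tested, none of them called, the median, the mean and the direction of the test differed in sign. Of the 17 lists not called, 11 had medians that changed sign with a library left out, among them the nuclear pore (0.038) and remodelling (0.036) without NSN replicate 2 and histone modifying enzymes (0.028) without SN replicate 1.

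**Figure D2:**
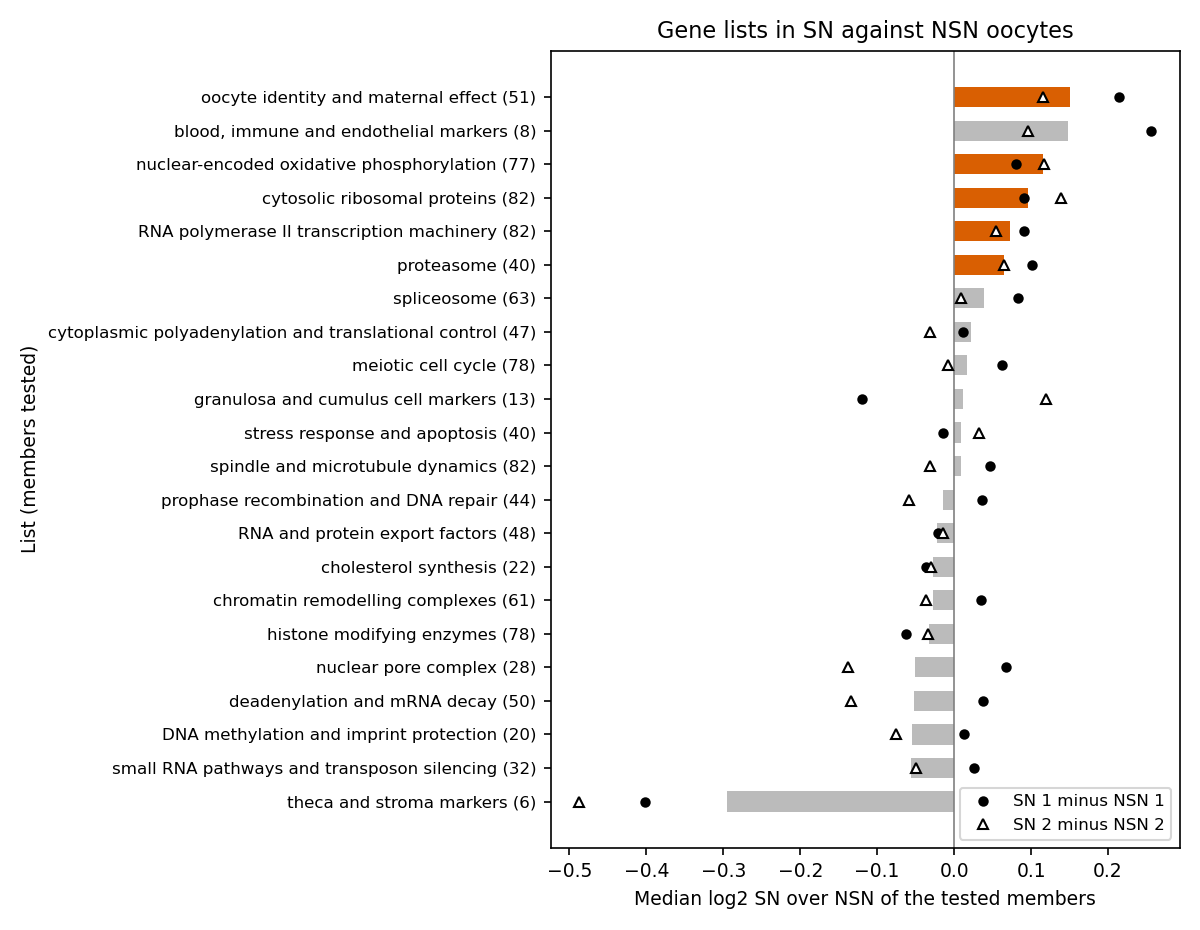
Median log2 of SN over NSN of the tested members of each list (bars; orange where camera with a preset correlation gave an adjusted p under 0.05), with the same median within replicate number 1 (filled circles) and replicate number 2 (open triangles). The 5 orange lists have medians from 0.07 to 0.15; none was called with an estimated correlation.

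Markers of other cells were measured apart. Inha, a granulosa cell hormone subunit, was at 11.4 and 4.03 CPM in NSN and 3.71 and 6.5 CPM in SN, and Amh, another granulosa hormone, had 11 and 2 counts in NSN and 0 and 7 in SN, a ratio of 0.472 for SN over NSN (95% exact interval 0.16 to 1.27). Inha was higher in SN without NSN replicate 1 (log2 0.343) and was called lower without SN replicate 2 (-1.05). Granulosa and cumulus markers had a median log2 of 0.01 over 13 tested members (camera adjusted p = 0.964), which moved to -0.369 without NSN replicate 2, -0.12 without SN replicate 2, -0.03 without SN replicate 1 and 0.069 without NSN replicate 1, with Fst at -1.32 (SE 0.67) and Hsd17b1 at -0.83 (SE 0.58). Theca and stroma markers had a median of -0.30 over 6 members (camera adjusted p = 0.507), with Pdgfra at -1.11 (SE 0.68) and Cyp11a1 at -0.30 (SE 0.24). With a library left out, that median ranged from -0.575 without SN replicate 1 to -0.295 without NSN replicate 1. These lists had 0 members called over all genes and 0 adjusted over the list alone. Blood, immune and endothelial markers had a median of 0.15 over 8 members (camera adjusted p = 0.185; fry adjusted p = 0.0286). The median was 0.44 without SN replicate 2, 0.242 without NSN replicate 2, 0.102 without NSN replicate 1 and 0.077 without SN replicate 1. Camera called this list with library size alone (adjusted p = 0.0246) and with no low-count filter (adjusted p = 0.0272), and with an estimated correlation its adjusted p was 0.947. Over all genes 0 of its members were called, and adjusted over the list alone 3 were: Lyz2 and Hba-a1 higher and Tek lower in SN. Lyz2 and Hba-a1 were also called over all genes without SN replicate 1, without SN replicate 2, with library size alone, with no low-count filter and on log2(TPM + 1) and log2(TPM + 0.1). Lyz2, a lysozyme of myeloid cells, had 0 and 1 counts in NSN and 27 and 35 in SN, a ratio of 54.4 (95% exact interval 9.4 to 2180). Hba-a1, an alpha globin gene with a near-identical neighbour, had 0 counts in both NSN libraries and 18 and 26 in SN, at least 12.9-fold higher against a floor of 3 counts over the class. Tek, an endothelial receptor, was at 6.36 ± 0.463 CPM in NSN and 4.06 ± 0.292 CPM in SN (SD, n = 2 each).

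The use of transcript models was compared within genes, apart from gene level. The test called a changed share of models in 30 of 7000 genes (diffSpliceDGE of edgeR, adjusted p under 0.05), and 494 genes had an unadjusted p under 0.05. The same test called 17 genes for replicate 2 against replicate 1. In simulated counts it made 16 false calls while recovering 65% of 60 changed genes, more false calls than the threshold of 0.05 allows. Rspo2, a secreted enhancer of Wnt signalling on chromosome 15 at 43020788 to 43171594, had the smallest adjusted p at 1.39e-06: a predicted model held 6.97% ± 0.274 of its counts in NSN and 0.00225% ± 0.00318 in SN (SD, n = 2 each), with 515 and 535.2 counts in NSN and 0 and 0.3 in SN. In Ddx50, an RNA helicase on chromosome 10 at 62615792 to 62658764, a predicted model held 15% ± 7.58 in NSN and had 0 counts in both SN libraries (edgeR adjusted p = 0.00145; SD, n = 2). In Tmem201, which encodes a protein of the inner nuclear membrane and lies on chromosome 4 at 149715375 to 149738072, a curated model rose from 0.00779% ± 0.011 in NSN to 21.3% ± 1.98 in SN (edgeR adjusted p = 0.00278; SD, n = 2 each). Of 8 alternative settings, Rspo2 was called in 6, and Ddx50 and Tmem201 in 1 each.

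No gene with a changed isoform share passed the test for total level, but edgeR called 0 of all 13426 genes there. Among the 30, 1 had an unadjusted p under 0.05, against 7.48% of all tested genes. The total of Rspo2 differed by a log2 of -0.11 (SE 0.10), that of Ddx50 by -0.19 (SE 0.12) and that of Tmem201 by -0.01 (SE 0.11). In 22 of the 30 genes a model was under 1 count in both libraries of one class and at 100 or more in both of the other. The model with the smallest p was a predicted one in 20 genes, and its share was higher in SN in 12 genes and lower in 18. The count of genes fell to 14 without NSN replicate 1, 0 without NSN replicate 2, 7 without SN replicate 1 and 6 without SN replicate 2, with 3, 0, 3 and 2 of the 30 among them, and to 0 among curated models alone, and it rose to 50 at a mean count of at least 50. With the replicate block the count was 2 and by limma's diffSplice 17, with 2 and 4 of the 30 among them. Models under 1 count in one library and at 100 or more in another numbered 681 between the NSN libraries, 618 between the SN libraries and 654 to 714 between libraries of different classes.

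**Figure D3:**
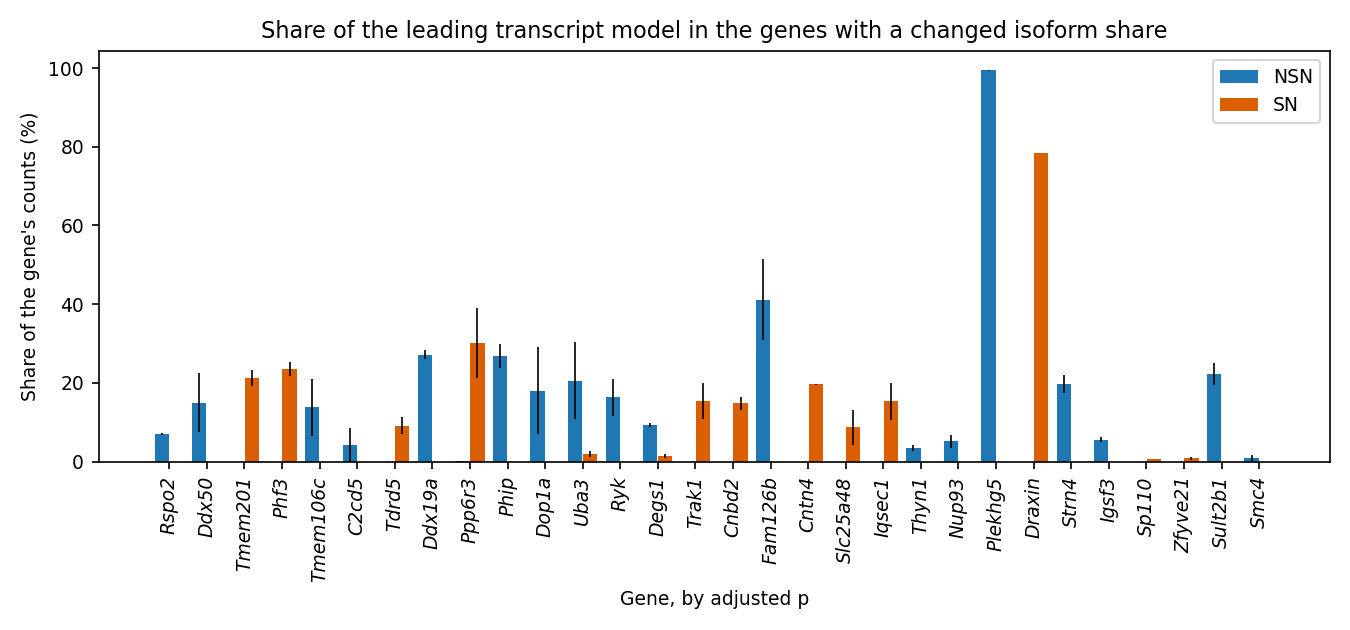
Share of each gene's counts held by the model with the smallest p, as the mean of 2 libraries per class with SD bars, in the 30 genes with a changed isoform share, ordered by adjusted p. The share is at or near 0 in one class for most genes, as in Rspo2 (6.97% in NSN against 0.00225% in SN) and Tmem201 (0.00779% against 21.3%).

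At the level of single transcripts, the edgeR test called 0 of 29835 transcripts, with 1930 at an unadjusted p under 0.05, 1004 higher and 926 lower in SN. DESeq2 called 1178 and limma-voom 0. In simulated transcript counts DESeq2 made 292 false calls, where edgeR made 12, so the 1178 may include many false calls. The transcripts with the smallest adjusted p (0.696 each) were predicted models of Phf3, Gpr1 and Ddx19a. That of Phf3, a nuclear PHD finger protein, had 0 counts in both NSN libraries and 1044.7 and 984.6 in SN. That of Gpr1, a chemerin receptor, had 484.4 and 472.7 counts in NSN and 1520 and 1622 in SN. That of Ddx19a, a helicase of mRNA export, had 609.5 and 594.1 counts in NSN and 0 in both SN libraries. Differences of this size were not called, so 0 calls do not show that large differences between transcripts were absent. The gene totals of Phf3 and Ddx19a differed by a log2 of only -0.072 (SE 0.093) and -0.142 (SE 0.096). Models under 1 count in one library and at 100 or more in another numbered 681 between the NSN and 618 between the SN libraries. Read assignment between models therefore cannot be told apart from a real change in these 2 examples. In the authors' deposited table, 4001 of 47854 transcripts have a p under 0.05, 2118 higher and 1883 lower in SN. After Benjamini-Hochberg adjustment applied here, 1003 transcripts of 858 genes in the authors' deposited table were under 0.05, 559 higher and 444 lower in SN.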

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

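The added trend, cyclic loess, diffSplice and curated-model settings were chosen after seeing the data. Genes called, 0 in the main test, numbered 46 by DESeq2, 15 with library size alone, 15 with no filter, 47, 45 and 33 by limma-trend on TPM (pseudocount 1, 0.1, and mean TPM of at least 1), 1 with the length and GC trend removed, and 2 to 289 with a library left out (2 without NSN replicate 1 or 2, 27 without SN replicate 1, 289 without SN replicate 2); limma-voom, the other scalings, the mean count of at least 50, the 2-fold threshold and cyclic loess gave 0. DESeq2's independent filtering left 898 genes. With a library left out, the deviation of the lone library of a class counted as a class difference. Library size alone moved the median log2 of all genes by -0.143, which lowered the medians of the 5 called lists by about as much; the cause of the other differences was not tested. Transcripts called were 1178 by DESeq2 and 0 by limma-voom, with the other scalings and filters and with each library left out; TPM, the 2-fold threshold, the trend removal and cyclic loess were not run for transcripts. Genes with a changed isoform share, 30 in the main test, were 50 at a mean count of at least 50 (26 shared), 17 by limma diffSplice (4 shared), 0 among curated models, where 3323 genes were tested, and 0 to 14 with a library left out (14 without NSN replicate 1, 0 without NSN replicate 2, 7 and 6 without SN replicates 1 and 2). Lists called, 5 in the main test, were 0 with the estimated correlation, 1 by fry (blood markers), 3 with library size alone (oocyte identity, ribosomal proteins and blood markers), 6 with no filter (the main 5 and blood markers), 1 with the length and GC trend removed (oocyte identity), 0 with cyclic loess, and 0 to 5 with a library left out (0 without NSN replicate 2 or SN replicate 1).

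With the replicate block, in which only 2 pairs share a number and no label says what it marks, genes called were 44, all higher in SN and among them Cradd, Mfap1b, Lcmt2, Crabp2, Cnpy4, Bloc1s2, Calm2, Grm2 and Tpm3, transcripts 0, isoform genes 2 and lists 5; with the trend removed as well, genes called were 82 and lists 1. Deviations of same-numbered libraries correlated at 0.029 across genes. DESeq2 and the block shared 12 genes.

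Reversed medians of the called lists were -0.064 and -0.016 for the oocyte and proteasome lists with cyclic loess; the proteasome median was also under 0 with the length and GC trend removed (-0.005) and with the block added (-0.003), where the test's direction stayed up. With a library left out, ribosomal proteins ranged from -0.036 without NSN replicate 2 to 0.261 (-0.025 without SN replicate 1) and oxidative phosphorylation from -0.008 without SN replicate 1 to 0.222 (-0.003 without NSN replicate 2). Of the 17 lists not called, 11 had medians that changed sign with a library left out, within -0.14 to 0.053 except for granulosa markers (-0.369 without NSN replicate 2, to 0.069), and 0 of the 17 were called. Genes with a changed sign were Ddx4 (-0.165 without SN replicate 2, to 0.394), Gdf9 (-0.072 without SN replicate 1, to 0.263; -0.197 with cyclic loess) and Zp3 (-0.037 with cyclic loess). Inha (-1.152 to 0.343) and Hsd17b1 (-1.42 to 0.159) reversed without NSN replicate 1. The cause was not tested. Ddx4 on TPM (-0.063, -0.068 and -0.063) and Gdf9 on TPM (-0.112 in each setting) and with library size alone (-0.052) were under 0 but above the median of all genes there (-0.133, -0.179 and -0.156 on TPM, -0.154 with library size). Of 1251 values of 70 named genes, 1130 kept their direction uncalled, 108 kept it and were called, and 13 changed sign. Genes near the floor are limited by depth.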

Other observations

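The tests below were chosen after the results were seen, except that of S100a8 and S100a9, and the gene families below were picked after their values were seen. Of the criteria by which the tests were read, 4 were revised after a first outcome and are given at the end. Members of 3 gene families, for which no list test was run, had fitted log2 values above 0, and edgeR called 0 of them with all libraries: all 6 tested Obox genes (median log2 0.47, SD 0.14 over genes, 3 at an unadjusted p under 0.05), all 6 tested Tcl1 family genes (median 0.41, SD 0.13, 4 at an unadjusted p under 0.05) and all 4 tested Oog genes (median 0.22, SD 0.17, 2 at an unadjusted p under 0.05). Without SN replicate 2 edgeR called Obox1, Obox2, Obox5, Obox7, Tcl1b1, Tcl1b2, Tcl1b3, Tcl1b5 and Oog1, and with the replicate block Obox2 and Obox5. With cyclic loess the family medians were 0.306, 0.256 and 0.03. Nlrp genes had a median of 0.085, with 9 of 12 higher in SN, and flipped with cyclic loess (-0.069). Oas1 genes had a median of 0.107 (SD 0.536), with 6 of 7 higher in SN, and flipped with cyclic loess (-0.099). Members of these families are close paralogs, so their counts are not independent of each other. Of all genes, 84.3% between a log2 CPM of 8 and 10 and 98.4% above 10 were higher in SN. Oog1 lay at 11.58, Obox2 at 11.12 and Tcl1b3 at 8.62. The families were not compared with other genes of their abundance, so a shared direction is not particular to them. Obox1 and Obox2 and the genes Tcl1b1, Tcl1b2, Tcl1b3 and Oog1 were among the 46 genes called by DESeq2, as was Hmgb2, a chromatin protein, at 407.6 ± 60.6 CPM in NSN and 615.8 ± 101 CPM in SN (SD, n = 2 each). The most abundant gene in SN was Clec16a, at 17756 and 15705 CPM in NSN and 28928 and 20088 CPM in SN.

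The most abundant genes were higher in SN, with a median log2 of 0.255 over the 125 genes above a log2 CPM of 10. With a trend with transcript length and GC content removed, the median was 0.223 (interquartile range over genes 0.115 to 0.314). Removed in this way, the trend accounted for little of the 0.255. By pair, SN replicate 1 then exceeded NSN replicates 1 and 2 by 0.303 and 0.385. SN replicate 2 exceeded them by 0.023 and 0.109, against 0.099 between the NSN libraries. What remained came mostly from SN replicate 1, so a class difference beyond the trend cannot be told from these values. The removal also ended 4 of the 5 list calls. Medians fell from 0.096 to 0.036 for ribosomal proteins and from 0.115 to 0.031 for oxidative phosphorylation (SD over genes 0.126 each). They fell from 0.073 to 0.051 for RNA polymerase II machinery (SD 0.176) and from 0.065 to -0.005 for the proteasome (SD 0.159). A shift of SN replicate 1 alone cannot be told apart from a shared one: without that library the median was 0.127, less than the 0.151 between the NSN libraries. The chromatin class of the oocyte may also contribute and stays open, since the 3 possible splits of the libraries are too few for a share under 0.05; the class split gave 0.255 and the highest other, by replicate number, 0.224. The replicate-number split also moved the ribosomal protein and oxidative phosphorylation lists more than the class did, which points to a structure of the libraries besides class.

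Models of one gene were seen in one class alone for 74 models, at 100 counts or more in both libraries of that class and under 1 in both of the other. A candidate explanation is the assignment of shared reads between similar models. Models under 1 count in one library and at 100 or more in another averaged 649.5 per pair within a class. Between classes they averaged 689.2, a ratio of 1.06. Differences of this kind thus also arose between libraries of one class. The 74 are few beside these means, so the ratio would stay near 1 whatever their source and cannot decide it. The chromatin class of the oocyte stays open, as the 3 splits are too few for a share under 0.05; the class split gave 74 and the highest other split 57. Reads that cross the junctions unique to such a model were not analysed here.

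Haemoglobin genes and Lyz2 had counts almost only in SN, where the alpha globin genes had 80 counts against 1 in NSN. Red blood cells or their RNA are a candidate source, although the oocytes had been denuded. The beta globin genes had 18 counts in SN against 1 in NSN, a ratio of 15.8 (95% exact interval 2.49 to 658). Beta globin counts belong to the pattern itself, so they are not independent evidence for this source. Neutrophils cannot be told apart from other sources of the 62 Lyz2 counts in SN, since S100a8 and S100a9 had 6 counts there, and macrophages or other white cells also stay open, since the 4 markers near 0 in NSN (Ptprc, Adgre1, C1qa and Cd74) had 12, too few to decide. Chance capture of rare molecules also stays open. In the class split, 8 genes had at most 1 count in each library of one class and 10 or more in both of the other. The highest other split gave 5. The 8 include Lyz2, Hba-a1 and Hba-a2, the genes to be explained, so the excess is no evidence against chance. Besides, 3 splits are too few for a share under 0.05. Expression of the haemoglobin genes and Lyz2 by the oocytes themselves was not tested.

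The criteria revised after a first outcome were these. The share of S100a8 and S100a9 counts over Lyz2 was 0.0968, which meets the bound of 0.1 written beforehand against neutrophils; that the upper 95% limit (0.223) also lie under the bound was required only after that outcome, because 6 counts are few, and it leaves neutrophils open. The 7 white cell markers were at first summed, with 1799 counts in SN and 1655 in NSN, which exceeded the Lyz2 count and would have counted in favour of white cells; C1qb, Cd68 and Csf1r were then left out because both classes had counts of them. The value without SN replicate 1 was first read against the spread over genes (interquartile range 0.035 to 0.202) and taken to argue against that library as the cause, then against the difference between the NSN libraries. The beta globin ratio was first taken over a floor of 3 counts, as 5.26, and both ratios exceed the bound of 2.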
